A study of Danio rerio with 27 samples.

How the data were processed

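Pooled whole larvae at 21 days post fertilisation were sequenced with Lexogen QuantSeq 3′ mRNA libraries from total RNA, per the labels, 1 library per pool. The number of larvae per pool, guide positions, aligner, counting tool, annotation version and use of molecular identifiers are not given in the sources used here. The genome builds danRer10 and GRCz11 are both named, per the submitters' processing notes, without a stated role. The deposited table holds raw read counts per gene in 27 library columns, described as counts per the labels and found to be whole numbers. Its further 27 columns hold CPM, which the authors computed from the same counts: each deposited CPM value equalled count over column total times 1e+06 within 5e-04. The table has 39988 entries, of which 118 symbols stand on more than 1 entry and 6006 are unnamed loci with 0.505 to 0.749% of the counts. The most abundant entry took 28.8% of counts on average. Groups were taken from the sample titles, and no label names a batch, tank or date.

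Total counts of 3377345 to 6238251 per library set the precision: 3 counts, the limit that a count of 0 allows, equal 0.481 to 0.888 CPM. Genes were tested with edgeR 4.0.16 in R 4.3.3 on the counts, with TMM factors (0.909 to 1.07), its default filter on expression (15521 genes kept), 1 mean per group over all 27 libraries, a robust quasi-likelihood fit and Benjamini-Hochberg adjustment per comparison at 0.05. The common biological coefficient of variation was 0.264. Within groups, Pearson's r of log2 CPM was 0.889 to 0.957 and chi-square per degree of freedom 4.51 to 25.5. The 10 comparisons were 8 between 2 groups and 2 interactions of knockout with background, the knockout change in PY minus that in WT. Tests, comparisons, alternatives, lists and the rule for named genes were fixed before the data were examined, except where stated.

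Of 41 gene lists, 40 had at least 5 tested members and were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over lists within a comparison. Of their symbols 1563 matched directly, 42 by an older name and 82 by a pattern, and 99 did not match and were not used here. Camera was repeated with an estimated correlation, and fry, which asks whether the genes of a list move on balance 1 way without comparing them with other genes, was run as well.

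Named genes were the targeted genes with yap1, up to 8 genes per direction and comparison with the largest change among those called at a mean of at least 5 CPM and without overlap between libraries, up to 4 per list, up to 8 of opposite change and up to 6 shared by the knockouts. The text names part of these, and the results of a few genes are not reported here. Targeted genes too low for edgeR had an exact permutation test, whose smallest possible p was 0.0079, or 0.029 within WT. Shared control libraries were handled with 20 simulations of unchanged groups, in which each gene was drawn independently, and by splitting the controls.

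The procedure was tested on simulated data in which 200 of 15521 genes were changed. Changes of 1.5-fold, 2-fold and 4-fold were recovered in 7.46, 31.3 and 77.3% of cases for PY against WT with SLC45a2-KO alone, in 4.48, 40.3 and 84.8% for TGR5-KO in PY, in 10.4, 43.3 and 86.4% for CYP7a1-KO in PY, in 4.48, 44.8 and 77.3% for TGR5-KO in WT and in 5.97, 32.8 and 69.7% for CYP7a1-KO in WT. They were recovered in 14.9, 44.8 and 77.3% for PY against WT with TGR5-KO, in 10.4, 29.9 and 80.3% with CYP7a1-KO, in 11.9, 31.3 and 80.3% between the knockouts in PY, in 0, 16.4 and 53% for the TGR5-KO interaction and in 0, 20.9 and 62.1% for the CYP7a1-KO interaction. The recovery asked of the interactions was lowered after these values were seen. False calls were 0 to 6.49% of calls. All simulated groups had the same spread and each gene was drawn independently. False calls from a spread that differs between PY and WT, or that genes share, are thus not covered.

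Alternatives were DESeq2 1.42.0, RLE factors, TMM without genes of over 1% of counts, no filter, a filter of 5 CPM in 4 libraries, only the groups compared, the replicate number as a block, counts thinned to the smallest library, a fit without robust estimation and leaving out each library in turn. Another 4, chosen after the data were seen, changed the WT control group in 3 comparisons and left out PY CYP7a1-KO libraries 1 and 2 together, which stood apart from libraries 3 to 5 of their group (chi-square per degree of freedom 15.85 to 25.46, against 9.059 to 14.84 among those 3). Replicate numbers do not pair libraries across groups: over 35 pairs of same-numbered libraries from the 8 comparisons between 2 groups the correlation was -0.104 to 0.0624, and 5 of 27 libraries correlated best with their own number. The order of genes was read from the GRCz12tu RefSeq assembly, used for this alone.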

Results

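The data were gene-level read counts from 3′ mRNA sequencing of pooled whole zebrafish larvae collected 21 days post fertilisation. Larvae were wild type (WT) or of the PY background, which carries more than 1 engineered change, among them overexpression of YAP, a growth-promoting transcriptional coactivator, in the liver, and which the labels describe as tumour-burdened and cachectic (wasting). In both backgrounds CRISPR/Cas9 was aimed at SLC45a2 alone, which served as a pigmentation marker, or at SLC45a2 together with TGR5, a bile acid receptor (gene gpbar1), or with CYP7a1, an enzyme of classical bile acid synthesis. The 6 groups held 4 libraries each in WT and 5 each in PY, 27 in all. Total counts ran from 3377345 to 6238251 per library (median 4533099), and 18150 to 20820 genes per library had a count. A gene at 0 could have held up to 3 counts, or 0.481 to 0.888 CPM (counts per 1e+06 counts of a library, without scaling for these floors), and these floors and the intervals of count ratios cover counting error only. Values are CPM scaled by TMM factors ± SD over libraries or log2 changes ± SE from edgeR. The p-values of single genes measure the spread between pools of larvae, as 1 estimate per gene shared by all 6 groups. Pools differed more in PY (Pearson's r of log2 CPM within groups 0.889 to 0.94) than in WT (0.939 to 0.957). The shared spread can thus be too small within PY and too large within WT. In fits of the 2 groups alone, on the same genes, 1500 and 1354 passed for TGR5-KO and CYP7a1-KO in PY, against 1761 and 2079. In WT 1899 and 2992 passed, against 1008 and 1804. Camera's p-values compare the genes of a list with other genes at a preset correlation of 0.01. This correlation was not taken from the pools, so they do not measure how a list varies between pools. Reads shared by near-identical copies could have been split by the counting, which is not described, so members of the complement c3a, chitinase, gamma-crystallin, globin and hsp70 families are uncertain as single genes.

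The first principal component of the 2000 most variable genes held 40.6% of the variance and parted PY from WT, and the PY knockouts lay between the other groups. Its mean was 43.5 ± 4.03 (SD, n = 5) in PY SLC45a2-KO, 19.4 ± 4.71 (n = 5) in PY TGR5-KO and 23.1 ± 4.28 (n = 5) in PY CYP7a1-KO. The 3 WT groups lay at -34.3 ± 1.05, -37.3 ± 0.724 and -36 ± 1.45 (n = 4 each). The second component (8.17%) parted WT TGR5-KO, at 18.4 ± 1.75, from WT CYP7a1-KO, at -25.7 ± 1.22.

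**Figure D1:**
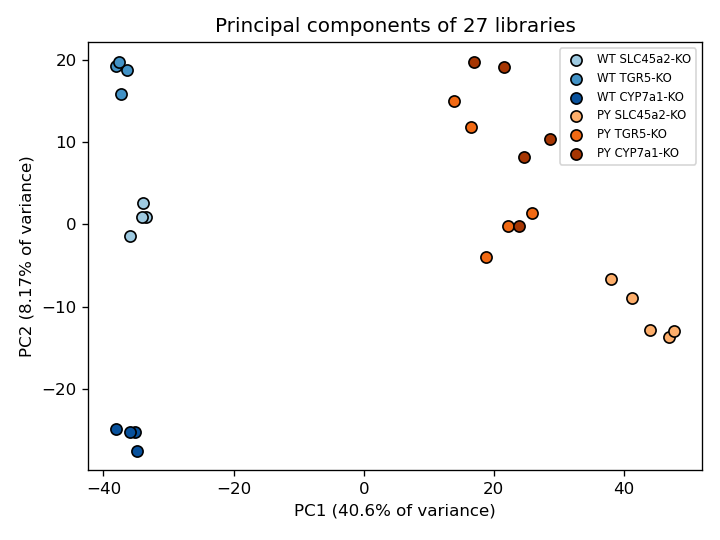
Scores of the 27 libraries on the first principal component (x axis, 40.6% of variance) and the second (y axis, 8.17%), 1 point per library, coloured by group. WT libraries lie to the left with group means of -34.3, -37.3 and -36, and the PY TGR5-KO and CYP7a1-KO libraries, with means of 19.4 and 23.1, lie between these and PY SLC45a2-KO at 43.5.

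The targeted genes were examined first. The cyp7a1 transcript was not lower in either CYP7a1-KO group: it stood at 44.9 ± 9.32 CPM (n = 4) in WT CYP7a1-KO, 30.1 ± 7.63 (n = 4) in WT TGR5-KO and 2.41 ± 1.69 (n = 4) in WT SLC45a2-KO. In PY it stood at 8.6 ± 3.11 CPM with SLC45a2-KO, 12.9 ± 4.26 with TGR5-KO and 12.3 ± 4.01 with CYP7a1-KO (n = 5 each). For slc45a2 there were 20 counts over all 27 libraries, with 19 libraries at 0, and for gpbar1 there were 45, with 14 libraries at 0. Neither passed in exact permutation tests of the 8 comparisons between 2 groups (p, both sides = 0.17 to 1, adjusted p = 0.58 to 1), and the lowest of these p-values for gpbar1 was that of 1 count in PY CYP7a1-KO against 13 in PY SLC45a2-KO. The yap1 transcript had 61 counts in PY SLC45a2-KO and 3 in WT SLC45a2-KO (3.05 ± 2.83 and 0.157 ± 0.314 CPM, n = 5 and 4, exact permutation p, both sides = 0.024, adjusted p = 0.48 over 24 tests of slc45a2, gpbar1 and yap1). PY SLC45a2-KO library 4 held 29 of the 61 counts, and without it the PY mean was 1.8 ± 0.542 CPM (n = 4, exact permutation p, both sides = 0.029, the smallest that these libraries can give). In PY TGR5-KO and PY CYP7a1-KO yap1 had 18 and 20 counts (0.899 ± 0.904 and 0.891 ± 0.644 CPM, n = 5 each, exact permutation p, both sides = 0.071 and 0.04 against PY SLC45a2-KO, adjusted p = 0.48 each). Guide positions are not given in the sources used here, and a 3′ tag outside the edited part of a gene checks nothing about the knockout.

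**Figure D2:**
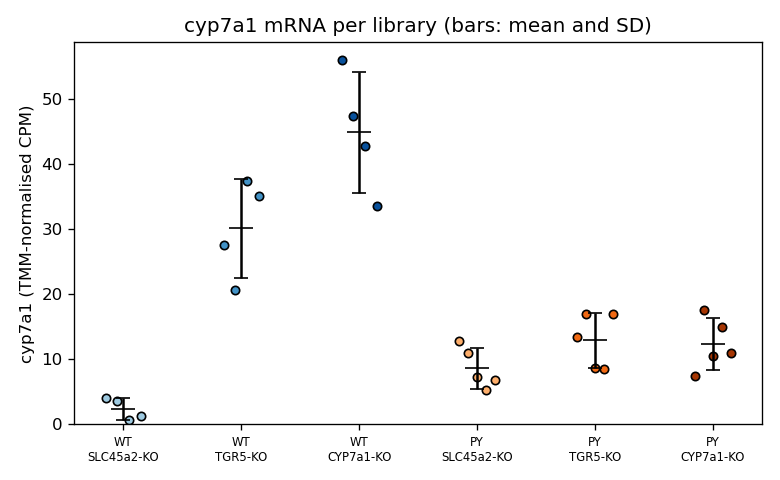
TMM-normalised CPM of cyp7a1 (y axis) in each library (points) of the 6 groups (x axis), with horizontal bars at the group mean and error bars of 1 SD (n = 4 per WT group, n = 5 per PY group). WT SLC45a2-KO averaged 2.41 CPM, WT TGR5-KO 30.1 and WT CYP7a1-KO 44.9, while the PY groups averaged 8.6 to 12.9.

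To examine the effect of the tumour background itself, PY was compared with WT in larvae with SLC45a2-KO alone. Transcripts of acute phase and inflammation were higher in PY. The liver-secreted binding protein igfbp1a, which holds insulin-like growth factors, was at 1950 ± 239 CPM (n = 5) in PY and 99.7 ± 7.81 (n = 4) in WT (log2 change 4.29 ± 0.16, adjusted p = 6.79e-27). Of 46 tested genes of acute phase and inflammation 35 rose and 2 fell (35 and 2 adjusted over the list alone, camera adjusted p = 8.38e-21). The complement genes among them included c3a.3 (3.21 ± 0.16), c9 (2.43 ± 0.20) and c5 (2.02 ± 0.17). The list called immediate early genes here, which respond to stress within minutes, also held heat shock and chaperone genes such as hsp70l, hsp90aa1.1 and dnajb1a. Its genes rose in 26 of 34 cases and fell in 3 (27 and 3 adjusted over the list alone, adjusted p = 2.02e-11). Among them was junba at 2.56 ± 0.22. Genes of bile acid transport and signalling rose in 10 of 21 cases and fell in 3 (10 and 5 adjusted over the list alone, adjusted p = 0.000856). Among them were abcb11b, the bile salt export pump (3.86 ± 0.30), and slc51a, a subunit of the bile acid exporter of the basolateral membrane (3.14 ± 0.19). Known YAP targets rose in 13 of 30 cases and fell in 2 (13 and 2 adjusted over the list alone, adjusted p = 0.00817). The target amotl2b was at 26.7 ± 5.2 CPM in PY and 6.2 ± 2.66 CPM in WT (n = 5 and 4). The target ctgfa went the other way, with under 0.75 CPM in PY libraries 1 and 2. Its other PY libraries held 1 count, where 18.4 were expected from WT. Hepatocyte markers rose in 28 of 54 cases and fell in 9 (28 and 9 adjusted over the list alone, adjusted p = 1.04e-05, adjusted p = 0.238 with an estimated correlation). Among them were the copper carrier cp at 3.78 ± 0.17 and the liver fatty acid carrier fabp10a at 1.96 ± 0.14. The hepatocyte and acute phase lists shared genes, c9, fga and fgb among them, so their results are not separate. Macrophage markers rose in 10 of 22 cases and neutrophil markers in 8 of 14, with 2 and 1 lower (10 and 2, and 9 and 1, adjusted over the list alone, adjusted p = 0.0198 and 0.0278, adjusted p = 0.169 and 0.326 with an estimated correlation).

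Transcripts of eye, skeleton, gut and pancreas were lower in PY than in WT, again with SLC45a2-KO alone. Eye markers fell in 44 of 48 cases and rose in 0 (45 and 0 adjusted over the list alone, camera adjusted p = 1.06e-30). The rod pigment rho changed by -1.84 ± 0.13 and the ultraviolet cone opsin opn1sw1 by -2.13 ± 0.17. Skeletal markers fell in 26 of 32 cases and rose in 1 (27 and 1 adjusted over the list alone, adjusted p = 2.62e-15). Among them were the bone matrix gene spp1 (-2.23 ± 0.17) and the cartilage collagen col11a2 (-1.98 ± 0.17). Of 23 exocrine pancreas markers 21 fell (21 adjusted over the list alone, adjusted p = 6.02e-17). Among them was the lipase cel.1 (-1.70 ± 0.14). Of 46 intestinal markers 28 fell and 1 rose (32 and 2 adjusted over the list alone, adjusted p = 2.02e-11). Among them were the chitinase chia.1 at -1.76 ± 0.13 and the goblet cell gene agr2 at -2.58 ± 0.21. Muscle structure genes fell in 38 of 81 cases and rose in 9 (42 and 9 adjusted over the list alone, adjusted p = 2.42e-06, adjusted p = 0.238 with an estimated correlation). The tropomyosins tpm1 and tpm2 changed by -1.55 ± 0.14 and -1.68 ± 0.12. Oxidative phosphorylation genes fell in 65 of 71 cases (65 adjusted over the list alone, adjusted p = 8.63e-20, adjusted p = 0.0865 with an estimated correlation). The ATP synthase ring gene atp5mc3b changed by -1.37 ± 0.14. Cholesterol synthesis genes fell in 16 of 26 cases and rose in 1 (18 and 2 adjusted over the list alone, adjusted p = 5.6e-05, adjusted p = 0.253 with an estimated correlation). Among them was msmo1 at -2.89 ± 0.38. Proliferation genes fell in 15 of 46 cases and rose in 1 (18 and 1 adjusted over the list alone, adjusted p = 0.000261, adjusted p = 0.204 with an estimated correlation), with the replication clamp pcna at -1.96 ± 0.20.

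Several genes were near 0 in 1 background with SLC45a2-KO alone. The haemoglobin scavenger hp had 274 counts in PY and 0 in WT (at least 81.5-fold higher against a floor of 3 counts over the group), and vat1 had 351 and 0 (at least 104-fold higher). The lens crystallin crygm2d1 had 0 counts in PY and 737 in WT (at least 275-fold lower), and the genes rif1 and mcama had 0 in PY (at least 52.7-fold and 41.1-fold lower). For neb, a giant protein of the muscle thin filament, the count ratio of WT to PY was 760 with a 95% interval of 136 to 30100. In PY TGR5-KO and PY CYP7a1-KO, however, neb had 562 and 454 counts, crygm2d1 341 and 374, rif1 76 and 52 and mcama 14 and 5. The near absence of neb, crygm2d1 and rif1 was thus that of PY SLC45a2-KO and not of all PY groups. This cannot be said of mcama, which stayed low in all PY groups. PY TGR5-KO library 2 held 9 of its 14 counts there, and the WT groups had 110, 39 and 31 counts. In WT TGR5-KO and WT CYP7a1-KO hp had 0 counts in each and vat1 had 27 and 4. Fitted changes of these genes depend on the prior count and are no bound: that of neb was -8.89 ± 0.97 and moved to -10.33 without PY SLC45a2-KO library 3. Across all genes 5531 of 15521 passed in edgeR's test, 2781 higher and 2750 lower, and 25 of 40 lists passed. With an estimated correlation 8 lists passed, those of acute phase, immediate early genes, eye, skeleton, exocrine pancreas, intestine, bile acid transport and YAP targets. The cyp7a1 transcript was higher in PY by 1.86 ± 0.37 (adjusted p = 8.65e-05) but changed by -0.77 against the mean of the 3 WT groups (adjusted p = 0.0135), a contrast added after the data were seen.

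**Figure D3:**
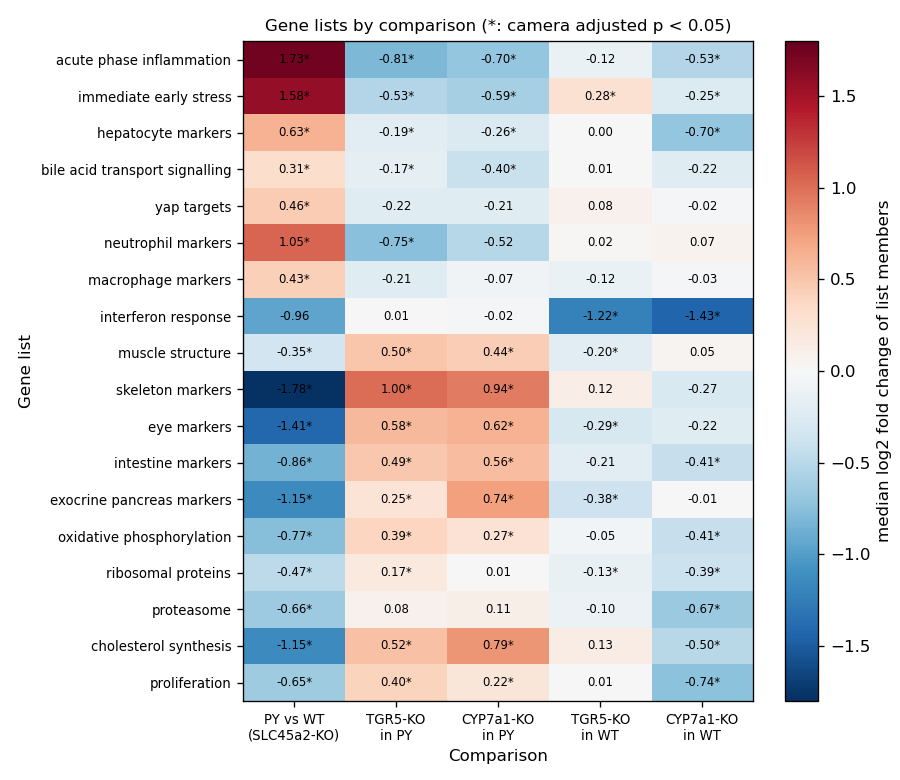
Median log2 fold change of the tested members (colour and printed value) of 18 gene lists (y axis) in 5 comparisons (x axis), with an asterisk where camera's adjusted p with its preset correlation passed 0.05. Acute phase genes had medians of 1.73 in PY against WT, -0.81 after TGR5-KO and -0.70 after CYP7a1-KO in PY, and skeletal markers had -1.78, 1.00 and 0.94.

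To ask what TGR5 knockout did in tumour-bearing larvae, PY TGR5-KO was compared with PY SLC45a2-KO. Muscle, eye and skeletal transcripts were higher after TGR5-KO, and inflammatory and immediate early transcripts were lower. Muscle structure genes rose in 37 of 81 cases and fell in 0 (44 and 1 adjusted over the list alone, camera adjusted p = 3.28e-21). Among them were tpm1 at 1.29 ± 0.13 and the skeletal actin acta1b, which went from 496 ± 124 to 1180 ± 131 CPM (n = 5 each, 1.26 ± 0.13). Eye markers rose in 26 of 48 cases (28 adjusted over the list alone, adjusted p = 2.62e-17). The change of rho was 0.75 ± 0.13 and that of opn1sw1 1.19 ± 0.16. Skeletal markers rose in 16 of 32 cases and fell in 1 (21 and 2 adjusted over the list alone, adjusted p = 8.24e-13), with col11a2 at 1.36 ± 0.16 and spp1 at 0.98 ± 0.17. Acute phase and inflammation genes fell in 24 of 46 cases and rose in 0 (31 and 1 adjusted over the list alone, adjusted p = 3.44e-17). Among them was c3a.3 (-0.96 ± 0.13). Immediate early genes fell in 14 of 34 cases and rose in 3 (16 and 3 adjusted over the list alone, adjusted p = 1.89e-07). They included fosb (-1.14 ± 0.19) and junba (-1.06 ± 0.18).

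Further groups changed in PY TGR5-KO, though their calls were lost with an estimated correlation. Oxidative phosphorylation genes rose in 27 of 71 cases (47 adjusted over the list alone, adjusted p = 2.59e-13, adjusted p = 0.148 with an estimated correlation). Among them was atp5mc3b at 0.72 ± 0.13. Intestinal markers rose in 15 of 46 cases and fell in 1 (21 and 2 adjusted over the list alone, adjusted p = 2.32e-08, adjusted p = 0.0611 with an estimated correlation). They included chia.1 at 0.79 ± 0.12. Neutrophil markers fell in 4 of 14 cases (6 adjusted over the list alone, adjusted p = 0.00114, adjusted p = 0.164 with an estimated correlation). Hepatocyte markers fell in 14 of 54 cases and rose in 4 (16 and 7 adjusted over the list alone, adjusted p = 0.00747, adjusted p = 0.467 with an estimated correlation). Among them was cp at -1.13 ± 0.14. Genes of bile acid transport and signalling fell in 6 of 21 cases and rose in 0 (7 and 1 adjusted over the list alone, adjusted p = 0.00718, adjusted p = 0.122 with an estimated correlation). They included abcb11b (-0.92 ± 0.24). Among single genes, the stress phosphatase subunit ppp1r15a fell by 1.68 (SE 0.17), the NF-kB inhibitor tnfaip3 changed by -1.89 ± 0.21 and igfbp1a went from 1950 to 570 ± 117 CPM (-1.78 ± 0.13, adjusted p = 4.09e-14). The collagenase gene mmp13a changed by -3.10 ± 0.63, but by -1.68 without PY SLC45a2-KO library 2, and lost its call with only these 2 groups in the fit (adjusted p = 0.0768). The neutrophil attractant cxcl8a changed by -6.55 ± 1.13, but by -5.50 without PY SLC45a2-KO library 2 and -8.75 without PY TGR5-KO library 4. In edgeR 1761 genes passed, 983 higher and 778 lower, and 26 of 40 lists did, 6 of them with an estimated correlation (muscle, eye, skeleton, acute phase, immediate early genes and pigment). The cyp7a1 transcript changed by 0.58 ± 0.29 (adjusted p = 0.198).

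To ask the same of CYP7a1, PY CYP7a1-KO was compared with PY SLC45a2-KO. Pancreatic, intestinal, eye and skeletal transcripts were higher after CYP7a1-KO, and inflammatory transcripts were lower. Exocrine pancreas markers rose in 17 of 23 cases (18 adjusted over the list alone, camera adjusted p = 1.24e-16). Among them was cel.1 at 0.91 ± 0.13. Intestinal markers rose in 20 of 46 cases and fell in 1 (23 and 1 adjusted over the list alone, adjusted p = 7.58e-14). The chitinase gene chia.1 went from 226 ± 26.5 to 563 ± 118 CPM (n = 5 each). Eye markers rose in 24 of 48 cases (27 adjusted over the list alone, adjusted p = 4.87e-15). Among them was opn1sw1 (1.37 ± 0.16). Skeletal markers rose in 15 of 32 cases and fell in 1 (20 and 2 adjusted over the list alone, adjusted p = 5.05e-09), including col11a2 (1.26 ± 0.16) and spp1 (0.92 ± 0.17). Acute phase and inflammation genes fell in 26 of 46 cases and rose in 2 (31 and 3 adjusted over the list alone, adjusted p = 6.74e-14). They included c3a.3 (-1.40 ± 0.13). Immediate early genes fell in 13 of 34 cases and rose in 2 (16 and 3 adjusted over the list alone, adjusted p = 1.6e-06), such as junba (-1.36 ± 0.19). Cholesterol synthesis genes rose in 10 of 26 cases (14 adjusted over the list alone, adjusted p = 4.29e-08, adjusted p = 0.192 with an estimated correlation), and hmgcs1, which makes the precursor of mevalonate, changed by 2.44 ± 0.51. The synthesis genes mvda and lss changed by 2.31 ± 0.55 and 2.22 ± 0.52.

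Muscle structure genes also rose in PY CYP7a1-KO, in 38 of 81 cases, and fell in 2 (40 and 2 adjusted over the list alone, adjusted p = 1.3e-15, adjusted p = 0.073 with an estimated correlation). Among them was tpm1 at 1.22 ± 0.13. Hepatocyte markers fell in 11 of 54 cases and rose in 3 (14 and 5 adjusted over the list alone, adjusted p = 0.0077, adjusted p = 0.447 with an estimated correlation). The change of cp was -0.81 ± 0.14. Bile acid transport and signalling genes fell in 6 of 21 cases and rose in 2 (6 and 2 adjusted over the list alone, adjusted p = 0.00272, adjusted p = 0.073 with an estimated correlation). Neutrophil markers did not pass as a list (median -0.52, adjusted p = 0.0653). Genes of the integrated stress response fell in 7 of 37 cases and rose in 1 (7 and 1 adjusted over the list alone, adjusted p = 0.0497, adjusted p = 0.435 with an estimated correlation). Their median, at 0.0444, differed in sign from their mean, at -0.0982, and from the test. The change of ppp1r15a was -1.92 ± 0.18, and the cell surface proteoglycan sdc4 changed by -1.54 ± 0.13 and igfbp1a by -1.86 ± 0.13 (adjusted p = 7.89e-15). The change of mmp13a was -4.09 ± 0.68, or -2.68 without PY SLC45a2-KO library 2, and hp, at -2.94 ± 0.77, lost its call without PY CYP7a1-KO library 3 (adjusted p = 0.0526) or 4 (adjusted p = 0.0557), or without its libraries 1 and 2 together (adjusted p = 0.0661). In edgeR 2079 genes passed, 1163 higher and 916 lower, and 21 lists did, 6 of them with an estimated correlation (exocrine pancreas, eye, acute phase, intestine, skeleton and immediate early genes). The cyp7a1 transcript changed by 0.50 ± 0.29 (adjusted p = 0.271).

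Whether genes altered by the tumour background moved the opposite way after knockout in PY was tested on the 5531 genes called in PY against WT. After TGR5-KO 91.3% of them had the opposite sign, against 58.2% (57.2 to 59.8) in 20 simulations of unchanged groups on shared controls, and after CYP7a1-KO 87.1% had, also against 58.2%. Over all genes tested, without this choice, the shares were 75.6% and 72.4%, against 55.5% in the simulations. The median move back was 0.48 on the log2 scale for TGR5-KO (simulated 0.0519) and 0.45 for CYP7a1-KO (simulated 0.0533), where the median background change was 1.12. Genes that passed in both tests with opposite signs numbered 1503 for TGR5-KO (3 with the same sign) and 1512 for CYP7a1-KO (20 with the same sign). Among those with the strongest evidence, igfbp1a was raised by 4.29 in PY and lowered by both knockouts, the tight junction gene cldn15lb changed by 2.61 ± 0.15, then by -1.29 ± 0.13 and -1.22 ± 0.13, and the iron-binding surface protein gene meltf by -4.66 ± 0.21, then by 2.35 ± 0.20 and 1.51 ± 0.20. Fold changes covaried across genes, which are not independent replicates, by -0.484 for TGR5-KO (simulated -0.0838) and -0.463 for CYP7a1-KO (simulated -0.0808). Split PY control libraries gave median shares of 86.1% and 82.5% of the genes called in each split (4396 in the median), and 755.5 (316 to 1089) and 779 (402 to 1028) genes that passed in both tests with opposite signs. With the background effect taken from the other knockout arm, which shares no library, the genes changed as well, to the 3608 and 3084 called there. The shares of these were 63.6% (highest simulated 51.6) and 79.4% (highest simulated 51.3), and the median move back was 0.17 and 0.38. The simulations drew each gene independently, so their ranges leave out variation that genes share within pools.

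**Figure D4:**
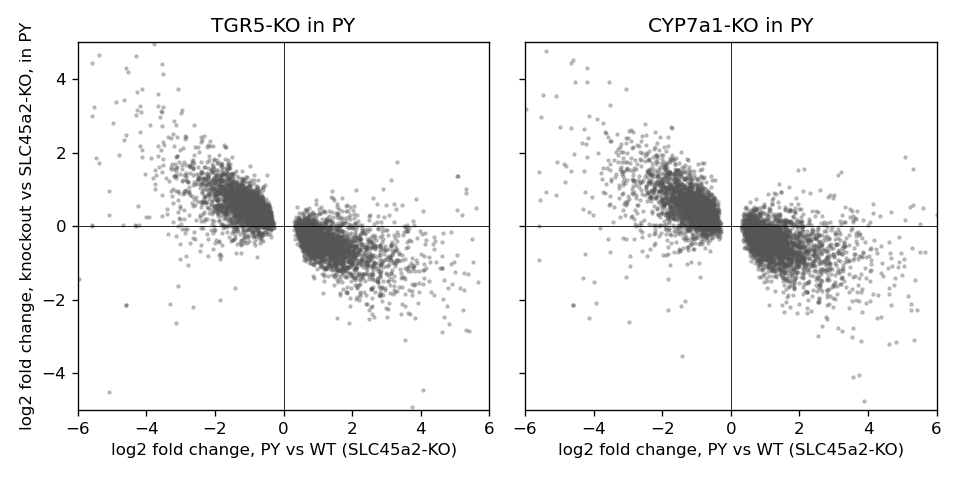
Log2 fold change of each of the 5531 genes called in PY against WT with SLC45a2-KO alone (x axis) against its log2 fold change after TGR5-KO (left) or CYP7a1-KO (right) in PY (y axis), 1 point per gene, with the axes limited to the range shown. Points fall mostly in the upper left and lower right of each panel, 91.3% for TGR5-KO and 87.1% for CYP7a1-KO, where shared control libraries alone gave 58.2% in simulations.

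The genes changed by the TGR5 and CYP7a1 knockouts in PY were then compared with each other. The muscle gene acta1b changed by 1.26 ± 0.13 after TGR5-KO and 1.13 ± 0.13 after CYP7a1-KO, and the proteoglycan gene sdc4 by -1.30 ± 0.13 and -1.54 ± 0.13. In all 1129 genes were called in both with the same sign, 647 higher and 482 lower, and 0 with opposite signs, where independent lists would share 73.7 and 45.9. Simulated unchanged groups shared 0, a count that says little, as almost no gene is called where nothing changed. The covariance of fold changes was 0.321 (simulated 0.0818) and their correlation 0.738 (simulated 0.476 to 0.511), and with the control libraries split the shared genes numbered 399.5 in the median (262 to 480), with up to 3 of opposite sign. In WT 173 genes were shared, 58 higher and 115 lower, and 47 had opposite signs (independent lists 19.9 and 39.4, covariance 0.173 against a simulated 0.103, but correlation 0.325, below the simulated 0.486 to 0.515), with 67.5 shared in the median after splitting the controls (62 to 73). The WT knockouts shared cyp7a1, which was higher in both, and the RNA helicase-like gene znfx1, the ubiquitin ligase rnf213a and the globin hbbe2, which were lower in both. Both sets of calls used the same WT SLC45a2-KO libraries, so a shift of these libraries and a change shared by the knockouts could not be told apart.

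A direct comparison of PY TGR5-KO with PY CYP7a1-KO asked whether the knockouts differed from each other. The lipoprotein lipase inhibitor angptl4 (0.87 ± 0.17) and apolipoprotein apoea (0.64 ± 0.13) were higher with TGR5-KO, and lpl itself (-0.80 ± 0.16), the kinase wnk1a (-1.42 ± 0.27) and cd74a, the invariant chain of class II antigen presentation, were lower, cd74a by -0.99 ± 0.16 (adjusted p = 0.00132). Exocrine pancreas markers were lower with TGR5-KO as a list (camera adjusted p = 7.68e-17, adjusted p = 0.069 with an estimated correlation), though 1 of 23 passed by itself (15 adjusted over the list alone). In edgeR 21 genes passed, 12 higher and 9 lower, against 1413 at an unadjusted p under 0.05, and 8 lists did, 0 of them with an estimated correlation. The count was 2 without PY TGR5-KO library 1, 7 without its library 5, 36 without PY CYP7a1-KO library 5, 3 with only these 2 groups in the fit, 70 in DESeq2, 95 without a filter, 37 without robust estimation and 12 without PY CYP7a1-KO libraries 1 and 2. With only these 2 groups in the fit 8 of 100 splits of the libraries, the real one included, gave as many genes, so chance was not excluded for these genes as a set. Without PY TGR5-KO library 1 the calls of angptl4 (adjusted p = 0.0558), apoea (0.0736), wnk1a (0.0558) and lpl (0.0558) were lost, without its library 5 those of angptl4 (0.0563) and apoea (0.0747), and without PY CYP7a1-KO library 1 those of apoea and lpl (0.0526 each), while cd74a kept its call. With only these 2 groups in the fit the calls of angptl4 (0.212), apoea (0.295), wnk1a (0.0599) and lpl (0.11) were lost too, and without PY CYP7a1-KO libraries 1 and 2 together those of apoea (0.0886), wnk1a (0.126) and lpl (0.208). The cyp7a1 transcript differed by 0.08 ± 0.28 (adjusted p = 0.962).

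To see the effect of TGR5 knockout without tumours, WT TGR5-KO was compared with WT SLC45a2-KO. Interferon-response genes, which restrict viruses, were lower after TGR5-KO, while cyp7a1 and glucokinase (gck) were higher. Of 29 interferon genes 16 fell and 0 rose (18 and 0 adjusted over the list alone, camera adjusted p = 1.28e-21, adjusted p = 0.00052 with an estimated correlation). Among them were the transcription factors irf7 at 8.95 ± 2.91 and 0.767 ± 0.464 CPM and stat1b at 10.1 ± 1.54 and 0.433 ± 0.402 CPM in SLC45a2-KO and TGR5-KO (n = 4 each). The antiviral gene ifit8 had 177 counts in SLC45a2-KO and 0 in TGR5-KO (at least 56.5-fold lower), and the globin hbbe2 had 4141 and 0 (at least 1320-fold lower). The ubiquitin-like modifier isg15 changed by -4.13 ± 0.59, or -4.76 without WT TGR5-KO library 3, and rsad2 by -4.33 ± 0.73, or -6.11 without its library 2. Autophagy and lysosome genes fell in 11 of 47 cases (16 lower and 1 higher adjusted over the list alone, adjusted p = 1.29e-09, adjusted p = 0.0698 with an estimated correlation). The autophagy kinase ulk2 changed by -1.48 ± 0.22. Circadian genes fell in 9 of 34 cases (10 adjusted over the list alone, adjusted p = 0.000279, adjusted p = 0.26 with an estimated correlation). Among them were the clock repressors per2 at -0.95 ± 0.20 and cry1ab at 2.24 ± 0.705 CPM against 9 ± 2.99 in SLC45a2-KO (n = 4 each). Genes of muscle atrophy fell in 4 of 31 cases (10 lower and 2 higher adjusted over the list alone, adjusted p = 0.00374, adjusted p = 0.249 with an estimated correlation), and the muscle ubiquitin ligase fbxo32 changed by -3.09 ± 0.59, or -3.77 without WT TGR5-KO library 2. The cyp7a1 transcript rose by 3.65 ± 0.36 (adjusted p = 3.67e-09), gck from 8.38 ± 3.28 to 101 ± 28.2 CPM and the RNA-processing gene srrt from 1.77 ± 0.466 to 25.6 ± 15.6 CPM (n = 4 each). In edgeR 1008 genes passed, 481 higher and 527 lower, and 13 lists did, of which interferon alone passed with an estimated correlation. With only these 2 groups in the fit 1853 genes passed. WT TGR5-KO was also set against WT CYP7a1-KO in place of WT SLC45a2-KO, a contrast added after the data were seen. In it a change shared by both knockouts cancels whatever its cause. In edgeR the sign of per2 turned and passed (0.91, adjusted p = 0.00124). The signs of cyp7a1 (-0.57, adjusted p = 0.149), isg15 (0.57, adjusted p = 0.703) and rsad2 (2.22, adjusted p = 0.223) turned without passing. The interferon, circadian and muscle atrophy lists did not pass between these knockouts (adjusted p = 0.862, 0.815 and 0.123), nor did ifit8 (0.162), stat1b (0.378), irf7 (0.987) and ulk2 (0.288), while the autophagy list was lower with TGR5-KO (adjusted p = 5.42e-07, adjusted p = 0.124 with an estimated correlation).

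To see the effect of CYP7a1 knockout without tumours, WT CYP7a1-KO was compared with WT SLC45a2-KO. Transcripts of liver, proteasome and interferon response were lower after CYP7a1-KO. The gene cyp1a, a target of the aryl hydrocarbon receptor, which senses foreign compounds, went from 22.7 ± 3.68 to 179 ± 46.7 CPM (n = 4 each, 2.98 ± 0.44, adjusted p = 9.12e-05) and the receptor's repressor ahrra changed by 4.60 ± 0.70, or 5.44 without WT SLC45a2-KO library 3. The list of foreign-compound and redox genes, which holds both, did not pass (5 of 42 higher and 8 lower, 5 and 10 adjusted over the list alone, median -0.157, adjusted p = 0.191). Hepatocyte markers fell in 28 of 54 cases and rose in 1 (33 and 1 adjusted over the list alone, camera adjusted p = 2.52e-20, adjusted p = 0.0361 with an estimated correlation). The change of cp was -1.67 ± 0.17, and the tryptophan-degrading tdo2a had 110 counts in SLC45a2-KO and 0 in CYP7a1-KO (at least 39.4-fold lower). Proteasome genes fell in 27 of 40 cases (31 adjusted over the list alone, adjusted p = 2.36e-17). Among them was psmd14 (-1.22 ± 0.20). Acute phase genes fell in 18 of 46 cases and rose in 1 (19 and 1 adjusted over the list alone, adjusted p = 6.87e-10), among them c3a.3 (-1.24 ± 0.16) and c5 (-1.31 ± 0.18). Interferon genes fell in 18 of 29 cases (21 adjusted over the list alone, adjusted p = 7.27e-17). Among them were irf7 at -3.48 ± 0.51 (-4.21 without WT CYP7a1-KO library 4), isg15 at -4.70 ± 0.62 and rsad2 with a count ratio of 119 (95% interval 32.7 to 992). Skin markers rose in 9 of 35 cases and fell in 1 (9 and 1 adjusted over the list alone, adjusted p = 2.76e-06). Proliferation genes fell in 15 of 46 cases (22 adjusted over the list alone, adjusted p = 1.43e-09, adjusted p = 0.0756 with an estimated correlation). The change of pcna was -1.23 ± 0.21. Oxidative phosphorylation genes fell in 25 of 71 cases (40 adjusted over the list alone, adjusted p = 1.18e-12, adjusted p = 0.188 with an estimated correlation). The globin hbbe2 was again at 0 counts (at least 1490-fold lower), and the cyp7a1 transcript rose by 4.22 ± 0.36 (adjusted p = 1.08e-10). In edgeR 1804 genes passed, 643 higher and 1161 lower, and 19 lists did, of which hepatocyte, proteasome, interferon, acute phase and skin passed with an estimated correlation. With only these 2 groups in the fit 2962 genes passed. In the contrast of the 2 knockouts given above, cyp7a1 (adjusted p = 0.149), isg15 (0.703), rsad2 (0.223) and irf7 did not pass, which does not show whether their shared change came from the knockouts or from the WT SLC45a2-KO libraries.

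**Figure D5:**
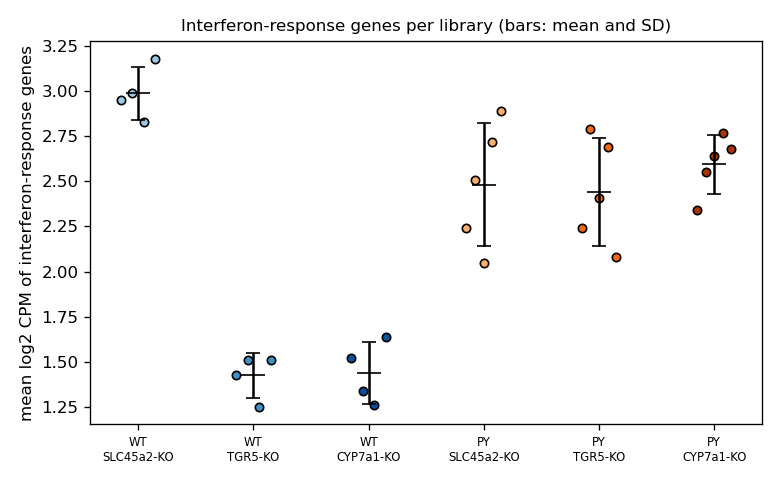
Mean log2 CPM of the tested interferon-response genes (y axis) in each library (points) of the 6 groups (x axis), with horizontal bars at the group mean and error bars of 1 SD (n = 4 per WT group, n = 5 per PY group). All 4 WT SLC45a2-KO libraries lie above the 8 other WT libraries.

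The background was also compared where each bile acid gene was targeted. With TGR5-KO in both, acute phase genes were again higher in PY, in 27 of 46 cases with 1 lower (28 and 1 adjusted over the list alone, camera adjusted p = 1.28e-16), and the complement gene c4b went from 6.08 ± 3.08 (n = 4) to 237 ± 66.1 CPM (n = 5, 5.29 ± 0.38). Skeletal markers fell in 15 of 32 cases (16 adjusted over the list alone, adjusted p = 2.44e-09). The change of spp1 was -1.43 ± 0.17. Interferon genes rose in 16 of 29 cases and fell in 1 (19 and 1 adjusted over the list alone, adjusted p = 1.72e-07), and bile acid transport genes rose in 10 of 21 cases and fell in 1 (11 and 1 adjusted over the list alone, adjusted p = 0.000451). Among them was slc51a at 1.87 ± 0.18. The globin hbbe2 had 6960 counts in PY and 0 in WT (at least 2040-fold higher), and gdi2, a regulator of Rab proteins, had 0 in PY and 348 in WT (at least 132-fold lower). Muscle structure genes rose in 28 of 81 cases and fell in 5 (32 and 7 adjusted over the list alone, adjusted p = 0.000449, adjusted p = 0.351 with an estimated correlation). In edgeR 3084 genes passed, 1777 higher and 1307 lower, and 27 lists did, 6 of them with an estimated correlation (acute phase, skeleton, interferon, liver glucose metabolism, glucocorticoid response and bile acid transport). The cyp7a1 transcript changed by -1.22 ± 0.28 (adjusted p = 0.00142).

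With CYP7a1-KO in both backgrounds, acute phase, hepatocyte and immediate early genes were higher in PY. Acute phase genes rose in 32 of 46 cases and fell in 0 (33 and 2 adjusted over the list alone, camera adjusted p = 3.07e-30). They included c3a.3 at 3.05 ± 0.16 and c9 at 3.19 ± 0.21. Hepatocyte markers rose in 35 of 54 cases and fell in 5 (37 and 6 adjusted over the list alone, adjusted p = 5.94e-26). Among them were cp, which went from 53.9 ± 3.51 (n = 4) to 1350 ± 262 CPM (n = 5), and tdo2a, from 0 to 316 counts (at least 97.2-fold higher). Immediate early genes rose in 22 of 34 cases (26 higher and 1 lower adjusted over the list alone, adjusted p = 1.41e-15). They included fosb at 3.04 ± 0.24. Neuronal markers fell in 23 of 40 cases (26 adjusted over the list alone, adjusted p = 1.64e-11), and eye markers in 26 of 48 cases (30 lower and 1 higher adjusted over the list alone, adjusted p = 1.59e-12, adjusted p = 0.056 with an estimated correlation). The iron hormone hamp, made in the liver, had 294 counts in PY and 0 in WT (at least 90.5-fold higher). In edgeR 3608 genes passed, 2062 higher and 1546 lower, and 16 lists did, 6 of them with an estimated correlation (acute phase, hepatocyte, immediate early genes, neuron, interferon and glucocorticoid response). The cyp7a1 transcript changed by -1.87 ± 0.28 (adjusted p = 2.29e-06).

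Whether TGR5-KO acted differently in PY and WT was tested as an interaction, the knockout change in PY minus that in WT. Muscle, eye, skeletal and interferon genes had more positive changes in PY than in WT, and immediate early genes more negative ones. Muscle structure genes differed upwards in 39 of 81 cases and downwards in 0 (46 and 1 adjusted over the list alone, camera adjusted p = 2.86e-24). Among them was tpm1 at 1.56 ± 0.20. Eye markers differed upwards in 28 of 48 cases (32 adjusted over the list alone, adjusted p = 2.08e-23), with rho at 1.05 ± 0.19. Interferon genes differed upwards in 15 of 29 cases and downwards in 1 (17 and 1 adjusted over the list alone, adjusted p = 1.44e-12), as stat1b did by 4.08 ± 0.83. This difference went with the WT SLC45a2-KO libraries, whose mean log2 CPM of these genes was 2.83 to 3.18 against 1.25 to 1.51 in WT TGR5-KO, while PY SLC45a2-KO (2.05 to 2.89) and PY TGR5-KO (2.08 to 2.79) overlapped. Immediate early genes differed downwards in 12 of 34 cases (16 lower and 1 higher adjusted over the list alone, adjusted p = 9.85e-10). They included atf3 at -2.85 ± 0.40. The differences of cyp7a1 and gck were -3.07 ± 0.46 (adjusted p = 2.25e-05) and -3.13 ± 0.54. In edgeR 1041 genes passed, 612 upwards and 429 downwards, and 19 lists did, 6 of them with an estimated correlation (muscle, eye, interferon, immediate early genes, skeleton and fatty acid oxidation).

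The interaction of CYP7a1-KO with the background held more genes. Intestinal markers differed upwards in PY in 24 of 46 cases and downwards in 1 (26 and 1 adjusted over the list alone, camera adjusted p = 4.2e-15). Among them was chia.1 at 1.93 ± 0.19. Interferon genes did so in 19 of 29 cases (21 higher and 2 lower adjusted over the list alone, adjusted p = 5.49e-10), with isg15 at 4.69 ± 0.74. Here too WT SLC45a2-KO stood apart from WT CYP7a1-KO (mean log2 CPM of these genes 2.83 to 3.18 against 1.26 to 1.64), while PY SLC45a2-KO (2.05 to 2.89) and PY CYP7a1-KO (2.34 to 2.77) overlapped. Cholesterol synthesis genes differed upwards in 13 of 26 cases (15 higher and 1 lower adjusted over the list alone, adjusted p = 1.32e-07, adjusted p = 0.211 with an estimated correlation). They included hmgcs1 at 3.48 ± 0.74 and msmo1 at 2.71 ± 0.54. Proliferation genes did so in 16 of 46 cases, with 1 downwards (21 and 1 adjusted over the list alone, adjusted p = 1.03e-07, adjusted p = 0.144 with an estimated correlation). Among them was pcna at 2.18 ± 0.29. Proteasome genes differed upwards in 24 of 40 cases, with 1 downwards (29 and 1 adjusted over the list alone, adjusted p = 3.07e-10, adjusted p = 0.108 with an estimated correlation). The differences of cyp1a and cyp7a1 were -3.73 ± 0.57 and -3.72 ± 0.46 (adjusted p = 2.21e-07). In edgeR 2761 genes passed, 1678 upwards and 1083 downwards, and 18 lists did, of which those of intestine and interferon passed with an estimated correlation.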

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

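All tests of the 3 patterns weighed here were chosen after the patterns were seen, and those of low depth and of a lower liver share were rewritten after earlier versions of them had given values, while the counts over other splits of the libraries and the 2 searches for deviating values were fixed before the data were examined.

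Single libraries lay far from the others of their group, by a gap test at the 5% level, in 54 of 594 groups of values. In 21 of them all other libraries of the group had 0 counts, where even 1 count passes this test, so the share cannot be held against the 1 in 20 that chance gives. WT CYP7a1-KO library 4 held 7 of these values and WT TGR5-KO library 1 held 5. The total of WT TGR5-KO library 3, 4.67 in units of 1e+06 counts, was 1 of them, and the rest were CPM of named genes. In PY CYP7a1-KO library 1 this held for slc45a2 (1.06) and noxo1a (1.33). For PY CYP7a1-KO library 4 the genes were gpbar1 (0.179) and cxcl8a (1.79). In PY CYP7a1-KO library 5 it held for gdi2 (6.14) alone. In PY SLC45a2-KO library 1 this held for ulk2 (25), ahrra (3.48) and gdi2 (2.32). For PY SLC45a2-KO library 2 the genes were cxcl8a (35.6), noxo1a (32.9) and mmp13a (90). The genes of PY SLC45a2-KO library 3 were neb (0.25) and fabp10a (6360). In PY SLC45a2-KO library 4 this held for yap1 (8.04) and slc51a (171). In PY TGR5-KO library 1 it held for tdo2a (7.07) alone. The genes of PY TGR5-KO library 2 were mcama (2.04) and tpm1 (336). In PY TGR5-KO library 3 it held for hp (25.3) alone. In PY TGR5-KO library 4 it held for cxcl8a (0.528) alone. In PY TGR5-KO library 5 it held for slc45a2 (0.243) alone. In WT CYP7a1-KO library 3 this held for itgb3a (0.329), col11a2 (189) and atp5mc3b (1300). For WT CYP7a1-KO library 4 the genes were slc45a2 (0.381), yap1 (0.763), mcama (4), ifit8 (1.14), mxb (0.191), cry1ab (11.4) and rpl6 (1280). The genes of WT SLC45a2-KO library 1 were hamp (0.224), cxcl8a (0.224), col11a2 (267) and cd74a (113). In WT SLC45a2-KO library 3 this held for yap1 (0.627) and ulk2 (64.2). For WT SLC45a2-KO library 4 the genes were slc45a2 (0.19), crp2 (69) and leg1.2 (66.4). The genes of WT TGR5-KO library 1 were slc45a2 (0.218), itgb3a (0.436), abcb11b (20.1), mxb (0.436) and itln1l (0.218). In WT TGR5-KO library 2 this held for yap1 (0.231), igfbp1a (65.7) and c4b (10.6). For WT TGR5-KO library 3 the genes were noxo1a (1.43), cldn15lb (74.2), lss (13.7) and rps6 (2180). In WT TGR5-KO library 4 it held for acta1b (1680) alone.

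The knockout effect differed between PY and WT, by the test of the interaction in edgeR, for 63 named genes with TGR5-KO and 69 with CYP7a1-KO. Values are the log2 change in PY minus that in WT, and those of genes near 0 in a group depend on the prior count. Both interactions used the same SLC45a2-KO libraries, so a control group that stands apart enters both. In WT hbbe2 had 4141 counts with SLC45a2-KO and 0 with either knockout, and in PY neb had 1, against 562 with TGR5-KO and 454 with CYP7a1-KO. Genes were named partly for large changes in these comparisons, so the numbers 63 and 69 are no independent evidence. The TGR5-KO differences below 0 were those of cxcl8a (-9.52), vat1 (-5.78), gck (-3.13), cyp7a1 (-3.07), srrt (-3.07), atf3 (-2.85), tnfaip3 (-1.90), fosb (-1.77), abcb11b (-1.57), slc51a (-1.27), cldn15lb (-1.22), c3a.3 (-1.22), ppp1r15a (-1.07), igfbp1a (-1.07), sdc4 (-0.90), c5 (-0.82) and cp (-0.78). Above 0 were the TGR5-KO differences of rpl6 (0.50), apoea (0.60), rps6 (0.63), angptl4 (0.77), gc (0.80), spp1 (0.81), atp5mc3b (0.89), leg1.2 (0.90), cel.1 (0.90), per2 (0.91), acta1b (0.96), cry1aa (1.01) and chia.1 (1.04). Further positive TGR5-KO differences were those of rho (1.05), lonrf1l (1.12), opn1sw1 (1.14), crybb1l2 (1.16), nfil3-2 (1.21), loxl2a (1.22), mt-nd4l (1.25), tpm2 (1.36), col11a2 (1.47), tpm1 (1.56), ulk2 (1.58), anpepb (1.86) and rnf213a (1.96). The TGR5-KO difference was also positive for crp2 (2.06), meltf (2.16), cry1ab (2.24), cbr1l (2.27), pdk2b (2.33), nr0b2a (2.57), znfx1 (2.63), pkz (2.91), irf7 (3.05), isg15 (3.50), stat1b (4.08), rsad2 (4.31) and mxb (5.17). To these positive TGR5-KO differences came mcama (6.04), rif1 (6.42), itln1l (6.97), ifit8 (8.03), neb (8.50), crygm2d1 (9.36) and hbbe2 (12.18). The TGR5-KO call of spp1 was lost, with the adjusted p in brackets, without WT SLC45a2-KO library 1 (0.0701), WT SLC45a2-KO library 3 (0.0918), WT TGR5-KO library 1 (0.0735), WT TGR5-KO library 2 (0.056), WT TGR5-KO library 4 (0.0625), PY SLC45a2-KO library 2 (0.0609), PY SLC45a2-KO library 5 (0.0532), PY TGR5-KO library 2 (0.0956) or PY TGR5-KO library 3 (0.0646), and also with all libraries thinned to the smallest (0.098). The TGR5-KO call of per2 was lost, with the adjusted p in brackets, without WT SLC45a2-KO library 4 (0.066), WT TGR5-KO library 3 (0.0654), PY SLC45a2-KO library 1 (0.0587), PY SLC45a2-KO library 2 (0.0595), PY SLC45a2-KO library 3 (0.0556), PY TGR5-KO library 3 (0.0773) or PY TGR5-KO library 4 (0.059), and also with all libraries thinned to the smallest (0.0677). The TGR5-KO call of cxcl8a was lost, with the adjusted p in brackets, without WT TGR5-KO library 4 (0.0713). The TGR5-KO call of mcama was lost, with the adjusted p in brackets, without PY TGR5-KO library 2 (0.0657). On the fold scale, fitted TGR5-KO differences moved by over 1.5 times, with the calls kept, from the values above for cxcl8a to -11.10 without WT SLC45a2-KO library 1, itln1l to 8.55 without WT TGR5-KO library 1, vat1 to -5.12 without WT TGR5-KO library 2, cxcl8a to -8.45 without PY SLC45a2-KO library 2, neb to 9.94 without PY SLC45a2-KO library 3, ifit8 to 7.14 without PY TGR5-KO library 2 and cxcl8a to -11.73 without PY TGR5-KO library 4.

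The CYP7a1-KO differences below 0 were those of cxcl8a (-8.27), mmp13a (-5.27), noxo1a (-3.74), cyp1a (-3.73), cyp7a1 (-3.72), ahrra (-3.69), tnfaip3 (-2.08), ppp1r15a (-1.89), sdc4 (-1.63), igfbp1a (-1.33), junba (-1.09) and cldn15lb (-0.64). Above 0 were the CYP7a1-KO differences of apoea (0.56), atp5if1a (0.70), fn1b (0.71), rpl6 (0.73), c9 (0.76), cp (0.87), rps6 (0.89), mt-nd4l (0.92), loxl2a (0.93), tpm2 (0.94), fosb (0.95), atp5mc3b (0.96) and cry1aa (0.98). Further positive CYP7a1-KO differences were those of lgals3bpb (1.04), agr2 (1.04), psmd14 (1.05), rho (1.05), nfil3-2 (1.12), ulk2 (1.14), cd74a (1.16), opn1sw1 (1.24), cel.1 (1.27), crybb1l2 (1.28), tpm1 (1.298) and c6ast3 (1.44). The CYP7a1-KO difference was also positive for col11a2 (1.49), gc (1.53), lonrf1l (1.63), wnk1a (1.76), rnf213a (1.84), chia.1 (1.93), spp1 (1.98), meltf (2.13), per2 (2.15), pcna (2.18), znfx1 (2.19) and leg1.2 (2.21). To these positive CYP7a1-KO differences came cbr1l (2.38), anpepb (2.70), msmo1 (2.71), pkz (2.77), stat1b (2.89), crp2 (3.04), irf7 (3.14), lss (3.19), hmgcs1 (3.48), mvda (3.58), isg15 (4.69), ifit8 (4.75) and mcama (5.05). Positive CYP7a1-KO values were also found for mxb (6.20), rsad2 (6.23), rif1 (6.94), neb (7.09), tdo2a (7.37), crygm2d1 (8.43) and hbbe2 (12.60). The CYP7a1-KO call of noxo1a was lost, with the adjusted p in brackets, without WT SLC45a2-KO library 2 (0.054), WT SLC45a2-KO library 4 (0.0585), WT CYP7a1-KO library 1 (0.0875) or WT CYP7a1-KO library 3 (0.0763). On the fold scale, fitted CYP7a1-KO differences moved by over 1.5 times, with the calls kept, from the values above for cxcl8a to -9.83 without WT SLC45a2-KO library 1, noxo1a to -4.66 without WT SLC45a2-KO library 3, mxb to 7.66 without WT CYP7a1-KO library 4, cxcl8a to -7.25 without PY SLC45a2-KO library 2, mmp13a to -3.86 without PY SLC45a2-KO library 2, neb to 8.52 without PY SLC45a2-KO library 3, mxb to 6.96 without PY SLC45a2-KO library 5, rif1 to 6.25 without PY CYP7a1-KO library 3 and cxcl8a to -12.28 without PY CYP7a1-KO library 4.

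The 3 WT groups differed in interferon-response genes, which stood high in WT SLC45a2-KO. The median of 29 such genes was 1.15 higher there, on the log2 scale, than in the mean of the other WT groups. A single deviating library is argued against, since 4 of 4 libraries lay above all 8 other WT libraries. More macrophages and neutrophils are argued against too, because 36 of their markers had a median of 0.00744 (bootstrap over genes -0.0654 to 0.205). This interval leaves out the spread between pools, and other immune cells were not part of this test. A shared tank, clutch or day of these pools could not be told apart from the group, as 0 labels name one, and an effect of the knockouts on interferon genes stays open too, untested.

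A set of 33 genes had counts in PY or in WT, both with SLC45a2-KO alone, and almost none in the other, 21 of them in PY and 12 in WT, and 6 and 8 of the 33 behaved so with TGR5-KO and CYP7a1-KO too. Low depth is argued against, since 134 genes chosen by the same rule on libraries 1 and 2 alone, the 33 among them, had a median of 0.118 of the expected count (bootstrap over genes 0.0719 to 0.136) in the other libraries of the group without them. Strain variants fixed between the backgrounds would part every PY group from every WT group alike. Only 6 and 8 of the 33 did so by these limits with the knockouts, but the limits had chosen the genes with SLC45a2-KO alone. Fewer can thus pass in other groups whatever the cause, so these counts do not decide it. In PY TGR5-KO and PY CYP7a1-KO neb had 562 and 454 counts, against 1 in PY SLC45a2-KO. There rif1 had 76 and 52, against 0. This argues against fixed variants for neb and rif1. For the rest fixed variants stay open: hamp, hp, itgb3a, noxo1a and vat1 had more counts in every PY group than in every WT group. Other linked strain variants stay open: 5 of the genes had another of the set within 5 tested genes, where 21 of 10000 random draws gave as many (permutation p = 0.002), but gene order could be read for 26 of the 33 (78.8%), too few for the test to decide. Older gene names were added to the matching after a first value was seen, and no biological explanation was tested.

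The PY knockout libraries lay between PY SLC45a2-KO and WT. Where no library was shared, the share of opposite changes fell from 91.3 to 63.6% for TGR5-KO and from 87.1 to 79.4% for CYP7a1-KO. The genes differed there too. These shares lay above the simulated values (at most 51.6 and 51.3%), which argues against shared control libraries as the whole cause if genes vary independently. The simulations drew each gene independently, so variation that genes share within pools is not covered, and its part was not tested. A lower share of liver RNA goes with the directions. Hepatocyte markers had medians of -0.194 after TGR5-KO (-0.372 to -0.0731) and -0.256 after CYP7a1-KO (-0.388 to -0.111). Their list shared genes such as c9 and fga with the acute phase list, which fell too, so they do not gauge liver RNA alone. All 6 lists of other tissues (muscle, eye, intestine, skeleton, neuron and skin) had bootstrap bounds above 0 after both knockouts. As the whole cause it would raise these lists alike, but 6 of 15 pairs had bounds that lay apart after both knockouts, mostly pairs with skeleton. The bounds resample genes and not libraries, so they leave out the spread between pools. Whether a lower liver share was the whole cause stays undecided. Skeletal markers had medians of 0.999 after TGR5-KO (0.768 to 1.21) and 0.94 after CYP7a1-KO (0.82 to 1.05), and neuronal markers 0.158 (0.083 to 0.319) and 0.262 (0.149 to 0.363). A change in the tissues that rose stays open. A deviating set of PY SLC45a2-KO pools cannot be told apart from the group, as 0 labels name a batch. An effect of the knockouts on the tumour background, which the design names, stays open as well.

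Other splits of the libraries of the groups compared were counted, up to 100 per comparison, with the real split included. Each was fitted on the groups compared alone with the 15521 genes kept over all libraries, and the real counts here differ from those of the fit over all 27 libraries, by over 1.5 times for CYP7a1-KO in PY (2079 there), TGR5-KO and CYP7a1-KO in WT (1008 and 1804) and the knockouts against each other in PY (21). For PY against WT with SLC45a2-KO alone 1 of 100 splits, the real one, gave as many genes (5776, highest other 2516), which makes chance unlikely. The same held, with 1 of 100, for TGR5-KO in PY (1500, highest other 28), CYP7a1-KO in PY (1354, highest other 6), PY against WT with TGR5-KO (3068, highest other 1601) and with CYP7a1-KO (2974, highest other 923), and the interactions of TGR5-KO (1209, highest other 309) and CYP7a1-KO (2682, highest other 979). In WT 1 of 35 splits gave as many for TGR5-KO (1899, highest other 2) and for CYP7a1-KO (2992, highest other 0). A batch that goes with the groups is not covered by any of these counts. Between PY TGR5-KO and PY CYP7a1-KO 8 of 100 splits gave as many as the real 3 genes, so chance cannot be excluded, and the highest of the other splits gave 48.3 times as many, which points to a structure of the samples other than the groups. The median of these splits was 0, and which structure it would be was not tested.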

How the results depend on the processing

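Chosen only after the results were seen were the 3 comparisons with another WT control group and the fit without PY CYP7a1-KO libraries 1 and 2 together.

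Over all alternatives, 1672 gene results gave 32805 values with the same direction and side of the threshold, 1023 that no longer passed, 359 that newly passed and 36 that reversed, and 400 list results gave 5768 such values (92.4%), 288 that no longer passed (4.62%), 2.71% that newly passed and 15 that reversed (0.24%). Of the counts and shares 371 values stayed and 45 moved. Sign changes with neither value past the threshold numbered 22 for genes and 150 for lists. Except where stated, the cause was not tested.

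Against the mean of the 3 WT groups, PY SLC45a2-KO reversed for cyp7a1 (-0.77, adjusted p = 0.0135), pkz (0.20) and the interferon list, which then passed as higher (adjusted p = 0.00445). With WT CYP7a1-KO as the control of WT TGR5-KO, 3277 genes passed, and the genes that reversed were cyp7a1 (-0.57), mxb (0.84), rsad2 (2.22), isg15 (0.57), crp2 (1.25), leg1.2 (0.91), nr0b2a (0.30), msmo1 (1.09), lonrf1l (0.31) and cry1aa (0.00889). The others were per2 (0.91), c6ast3 (0.0423), crybb1l2 (0.013), fn1b (0.63), gc (1.301), ddit4 (0.0652), anpepb (0.21), atp5if1a (0.45), rpl6 (0.31) and rps6 (0.36). A reversed value need not pass: in edgeR the adjusted p of per2 was 0.00124, but that of cyp7a1 0.149 and that of isg15 0.703. Lists that reversed then included those with adjusted p-values of 0.000104 (acute phase and ribosomal proteins), 0.862 (erythroid), 0.815 (fatty acid oxidation), 4.22e-13 (hepatocyte), 0.00193 (integrated stress), 0.018 (intestine), 2.06e-07 (oxidative phosphorylation) and 9.14e-09 (proteasome). Those of them that passed lost their calls in camera with an estimated correlation (adjusted p = 0.124 for hepatocyte and proteasome up to 0.645 for ribosomal proteins). With WT TGR5-KO as the control of WT CYP7a1-KO, again 3277 genes passed, and ifit8 (3.53), znfx1 (0.60), rnf213a (0.35), nfil3-2 (0.14), cbr1l (0.0154), ulk2 (0.35), cyp8b1 (-0.80), pdk2b (1.08), loxl2a (0.13), pkz (0.49), irf7 (0.0232), lgals3bpb (0.0397), mt-nd4l (0.023) and srgn (0.92) reversed, as did the lists of circadian (0.815), exocrine pancreas (0.038, or 0.645 with an estimated correlation) and interferon genes (0.862). In these 2, which are 1 contrast with its sign turned, a change shared by the knockouts cancels whatever its cause, so a lost call there does not tell a shift of WT SLC45a2-KO from a shared effect. In both hbbe2 had no value, with 0 counts on both sides.

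The number of genes between PY TGR5-KO and PY CYP7a1-KO, 21, moved to 70 in DESeq2, 95 without a filter, 3 with only the groups compared, 37 without robust estimation, 12 without PY CYP7a1-KO libraries 1 and 2, and 2 to 36 with 1 library left out. Its lists moved from 8 to 3 with fry and to 7 to 13 with 1 library left out, and the ribosomal list reversed without libraries 1 and 2 (adjusted p = 0.536). With only the groups compared 1853 genes passed for TGR5-KO and 2962 for CYP7a1-KO in WT. With an estimated correlation the lists that passed numbered 8, 6, 6, 1, 5, 6, 6, 6, 2 and 0, in the order PY against WT with SLC45a2-KO alone, TGR5-KO and CYP7a1-KO in PY, the same in WT, PY against WT with TGR5-KO and with CYP7a1-KO, both interactions, and the knockouts against each other.

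The share of opposite change was 86.1% for TGR5-KO and 82.5% for CYP7a1-KO with split controls, 63.6% and 79.4% with the background effect of the other arm, 75.6% and 72.4% over all genes tested, and 90.2 to 92.4% and 83.9 to 88.9% with 1 library left out. Genes shared by the knockouts numbered 399.5 in PY and 67.5 in WT in the median of split controls, where fewer control libraries enter each comparison. With the replicate number as a block, counts of genes were 5288, 1689, 1975, 986, 1767, 2849, 3623, 992, 2631 and 23 in the order above. Depth limits slc45a2 and gpbar1, with 20 and 45 counts in all.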

Other observations

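The comparison of the WT knockouts with each other was chosen only after the WT results were seen. In WT TGR5-KO against WT CYP7a1-KO, transcripts of liver, cell division, proteasome and respiration were higher, and those of autophagy, skin and muscle were lower, though these lists all lost their calls with an estimated correlation (adjusted p of 0.124 to 0.5). In edgeR 3277 genes passed, 1839 higher and 1438 lower. Hepatocyte markers rose in 29 of 54 cases and fell in 2 (camera adjusted p = 4.22e-13, adjusted p = 0.124 with an estimated correlation), with the copper carrier cp at 1.32 and the liver fatty acid carrier fabp10a at 1.06. Proliferation genes rose in 19 of 46 cases (adjusted p = 1.82e-09, 0.124 with an estimated correlation) and proteasome genes in 24 of 40, with 1 lower (adjusted p = 9.14e-09, 0.124 with an estimated correlation), among them psmd14 (0.86). Autophagy genes fell in 17 of 47 cases (adjusted p = 5.42e-07, 0.124 with an estimated correlation). Oxidative phosphorylation genes rose in 26 of 71 cases (adjusted p = 2.06e-07, 0.437 with an estimated correlation). Skin markers fell in 13 of 35 cases and rose in 2 (adjusted p = 8.35e-05, 0.124 with an estimated correlation), and muscle structure genes fell in 20 of 81 and rose in 4 (adjusted p = 0.000239, 0.5 with an estimated correlation). The foreign-compound response gene cyp1a changed by -3.30 (adjusted p = 1.85e-05), the clock repressor cry1ab by -1.90 and glucokinase, gck, by 2.71.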
